A study of Rattus norvegicus with 7 samples.

How the data were processed

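Total RNA from primary rat (Wistar) hippocampal neurons and astrocytes, cultured for 24 h with or without grape seed extract, was isolated by the authors with a silica-membrane kit. They amplified and biotin-labelled 100 ng in a two-cycle cRNA procedure and hybridized it to Affymetrix rat arrays, 1 array for each of 7 combinations of cell type and dose. The values used are the signal intensities as deposited, on a linear scale, which the authors computed per array with the GCOS software and scaled to a common target. The GCOS version and settings are not given in the sources used here. The 2%-trimmed means of the 7 arrays lay between 500.731 and 500.874, within the 10% allowed, so the scale was kept. No pair of arrays held identical values and every column was matched to a sample.

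Of 8799 probe sets, 59 control probe sets were left out of the comparisons, which left 8740. Gene symbols came from the platform annotation and were looked up by gene ID in a RefSeq table, where 6985 were found and none was changed. A single symbol was given for 7006 probe sets, several for 308 and none for 1426, for 4736 distinct symbols. Signals below the 25th percentile of all signals (17.9) were raised to it and log2 was taken, so a fold against such a signal is a lower bound. Between 23.3% and 27.2% of probe sets on each array were at that floor. A probe set entered a comparison within a cell type if its mean log2 signal there was above the median of all signals (79.9), which kept 4453 in neurons and 4252 in astrocytes. The comparison of cell types and the dose trends used the 4709 that met this in either cell type. These choices, the comparisons, the gene lists and the rule for naming genes were fixed before the data were examined.

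Neurons were compared with astrocytes over 3 and 4 arrays (5 residual degrees of freedom). A dose trend was fitted as a slope on log10 of the dose in µg/ml plus 1, with an intercept and a slope for each cell type over the 7 arrays (3 residual degrees of freedom), and the slopes of the cell types were compared in the same fit. These fits used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trended prior), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each treated array was also set against the untreated array of its cell type, as a log2 change without a test, and probe sets at 2-fold or more were counted. An array was said to stand apart in a probe set at least 2-fold above or below every other array of its cell type. With 1 array per combination, the number of arrays limits the precision of every value.

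There were 24 gene lists, for stress, inflammation, metabolism, cell cycle and markers of cell types, with each gene represented by its brightest probe set. For a list with at least 5 measured genes, the median log2 change was ranked among 10000 random lists of the same size matched on signal in 10 bins (seed 1), which describes these arrays and is no test. Genes were named by this rule. For the cell types, the 10 largest differences each way whose arrays did not overlap were taken. For astrocytes, the 12 each way in which the 100 µg/ml array stood farthest apart and the 5 each way in which all treated arrays differed 2-fold from the untreated one were taken. For neurons, the corresponding numbers were 10 and 4. Fewer were named where fewer met the rule. The rule added Il6, the 3 members of each list with the largest change at the highest dose, the 10 smallest p of a dose trend, and Nefl, Map2, Mbp and Col1a1. Gfap and Cd68 were also fixed but not analysed here. Other genes named in the text were chosen after their values were seen.

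The fits were tested on simulated data with 4709 probe sets. The noise was Gaussian with an SD of 0.134 log2 for every probe set, the median SD among the neuron arrays. Each run held 100 changes of size 1 and 100 of size 2, in log2 or in log2 per unit of the trend. For cell types and for astrocyte trends 100 of each size were recovered, with 16 and 6 false calls. Astrocyte changes from 0 to 1 µg/ml had an SD of 0.369 over probe sets. The simulation thus checks the calculation and does not show how well the fits work on these arrays. Alternatives tried were quantile normalization, no floor, no filter, a filter at the 75th percentile (435.7), the mean over the probe sets of a gene, the mean of all lower doses as reference, ranked and untransformed doses, a constant variance prior, each cell type fitted alone, dose as a block over the 6 arrays at shared doses, and leaving out each array. Centring changes on their median, the 1 µg/ml array as reference and scaling to the poly-A spike-ins were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.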

Results

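Gene expression was measured in primary cultures of rat (Wistar) hippocampal neurons and hippocampal astrocytes after 24 h with grape seed extract, a plant extract rich in polyphenols. Neurons received 0, 1 or 10 µg/ml and astrocytes 0, 1, 10 or 100 µg/ml, on 7 Affymetrix arrays, 1 for each of the 7 combinations of cell type and dose. The precision is limited by that number: no combination was repeated, so no value at a single dose has an error, and a change between single arrays is given as a size without a test. Signals are the authors' intensities, scaled so that the 2%-trimmed mean lay between 500.731 and 500.874 on every array. The median signal was 87.7, 87.3 and 84.6 in neurons at 0, 1 and 10 µg/ml, and 84.1, 79.9, 73.4 and 65.4 in astrocytes at 0, 1, 10 and 100 µg/ml. Across probe sets, the log2 signals of the 3 neuron arrays correlated at Pearson's r of 0.987 to 0.988, the astrocyte arrays at 0 and 10 µg/ml at 0.974, and the astrocyte array at 100 µg/ml with the other astrocyte arrays at 0.931 to 0.951. Probe sets are not independent replicates.

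The first comparison asked how the 2 kinds of culture differed, over all doses. Among the genes higher in neurons by the largest amounts, Nell2, a secreted protein of neurons, had a mean signal of 3782 ± 232 (SD, n = 3) against 18.9 ± 2.90 (SD, n = 4) in astrocytes, and Gap43, the growth cone protein, 7049 ± 262 (n = 3) against 219 ± 68.5 (n = 4). Chgb, Dync1i1, Camkv, Nefl, Gabrb2, Sv2b, Ptpn5 and Slc32a1 completed the 10 largest differences in that direction. Higher in astrocytes by the largest amounts were Apod, a lipid-binding secreted protein, at 6364 ± 897 against 30.9 ± 6.35 in neurons, Igf2, a growth factor, at 10618 ± 686 against 95.1 ± 14.2, and Mbp, the myelin basic protein, at 3932 ± 906 against 57.8 ± 12.6. Gpc3, Aldh1a2, Crabp2, Gng11, Ptgds, Aebp1 and Igfbp6 completed that set. In limma fits the difference was 7.60 log2 for Nell2 (adjusted p = 3.38e-07), 5.06 for Gap43 (4.73e-06), -7.70 for Apod (3.55e-07) and -6.08 for Mbp (1.66e-06). In each case all arrays of one cell type lay above all arrays of the other, which the rule for naming genes required, along with an adjusted p below 0.05.

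**Figure D1:**
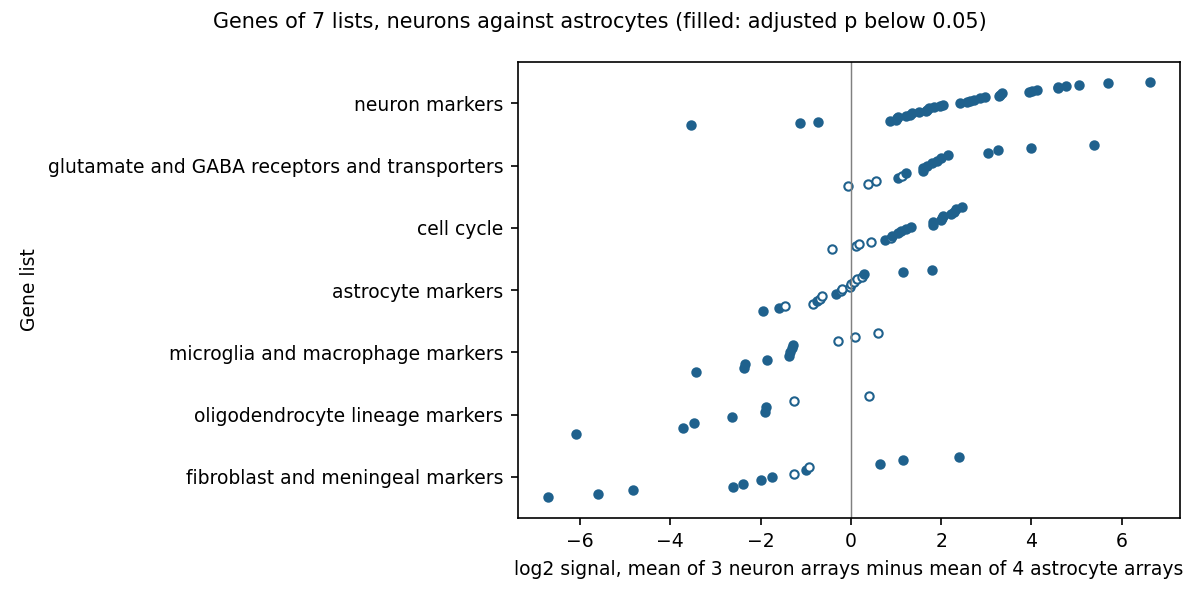
Difference in mean log2 signal between the 3 neuron arrays and the 4 astrocyte arrays for each measured gene of 7 lists, 1 point per gene, filled where the adjusted p from limma is below 0.05. Of the 35 neuron markers, 31 lie to the right as filled points and 3 to the left, and no filled point of the oligodendrocyte lineage or microglia lists lies to the right.

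Of 35 measured neuron markers, 31 were higher in neurons, such as Nefl (5.69 log2) and Map2 (1.98), and 3 were lower (adjusted p below 0.05, limma). Those 3 were Calb1 and Scg2, a calcium-binding protein and a secretory granule protein, and Nefh, a heavy neurofilament subunit (log2 differences of -1.13, -0.74 and -3.54). Of 17 genes for glutamate and GABA receptors and transporters, 13 were higher in neurons, among them Gria1 (3.26) and Gabrb2 (5.39), and 14 passed when adjusted over the list alone. Cell cycle genes were also higher in neurons, 15 of 20 (16 adjusted over the list alone), with Ccnb1 at 2.28, Top2a at 2.01 and Stmn1 at 1.81. The astrocyte arrays carried higher signals for markers of several other cell types. All 6 oligodendrocyte lineage genes past the threshold, of 8 measured, were lower in neurons, as were 8 of 11 microglia and macrophage genes, including C1qb (-3.43) and Cd53 (-2.33), and 8 of 13 fibroblast and meningeal genes, including Col3a1 (-4.82) and Col1a1 (-2.38), while Thy1, Igfbp2 and Fmod of that list were higher in neurons. Adjusted over each list alone, these counts were 31 and 3 for neuron markers and 6, 8 and 8 for the glial, microglial and fibroblast lists.

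Among 18 astrocyte markers, S100b (-1.96), Agt, Sparcl1 and Apoe were lower in neurons, whereas Slc1a3 (1.79), a glutamate transporter, Aqp4 (1.16), a water channel, and Cst3 were higher, and adjusted over the list alone 6 were lower and 3 higher. Interferon response and antigen presentation genes were lower in neurons, 7 of 14 (10 adjusted over the list alone), such as Psmb8 (-1.77) and Irf7 (-1.49), as were 17 of 37 extracellular matrix genes against 3 that were higher (19 and 3 adjusted over the list alone). In all, limma called 1423 of 4709 probe sets, 848 higher and 575 lower in neurons, and 367 of the calls differed at least 4-fold. The spread used is that between arrays of one cell type at different doses, so it holds the dose effect too. The differences hold it as well, and 100 µg/ml was given to astrocytes only. At 10 µg/ml the interferon list had a median log2 change of 1.05 in astrocytes and -0.44 in neurons. Its difference between cell types is therefore not one of untreated cells. The count was 937 without the neuron array at 0 µg/ml and 2086 without the astrocyte array at 100 µg/ml. It was 892 and 795 with a stricter signal filter and with 1 value per gene, where fewer items were tested.

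The second comparison asked what the extract changed in neurons, where the interferon response and antigen presentation list had a lower median in both treated arrays. Its median log2 change was -0.25 at 1 µg/ml and -0.44 at 10 µg/ml, below all 10000 random lists of the same size and signal at both doses. RT1-S3, a class I histocompatibility gene, had signals of 256, 122 and 116 at 0, 1 and 10 µg/ml. Irf7, a transcription factor induced by interferon, had 266, 195 and 142, Gbp2 had 625, 529 and 354, and Rsad2, an antiviral protein, had 338, 240 and 187. Of the 14 measured genes, 2 were at least 2-fold lower at 1 µg/ml and 1 at 10 µg/ml, and some were slightly higher. Both doses were set against a single untreated array, so a high value there would lower both, and the median at 10 µg/ml was -0.31 against the mean of both lower doses. The microglia and macrophage list had medians of -0.32 and -0.15 at these doses (percentiles of 0.01 and 8.06 among random lists). Other lists that were low at 1 µg/ml were neuron markers (median -0.12, percentile 0.02), immediate early genes (-0.12, 0.47) and glutamate and GABA genes (-0.17, 0.56), with percentiles of 39.7, 76.9 and 23.1 at 10 µg/ml.

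At 1 µg/ml, 25 of 4453 probe sets differed at least 2-fold from the untreated neurons (12 higher, 13 lower), and at 10 µg/ml 34 did (13 higher, 21 lower). The genes at least 2-fold apart from both other neuron arrays at 10 µg/ml were mostly dim: Cacnb1, a calcium channel subunit, was higher (67.8, 77.2 and 156), and Crybb2 (125, 116 and 40.6), Gjb5, Thpol1, Ptgir, Smg6, Cgrrf1, Stk25 and Scfd2 were lower. Thpol1 had a log2 change of -1.34 at its brightest probe set and 0.03 as the mean over its probe sets. Glycam1, Wdr62, Nppa and Foxe1 were at least 2-fold higher in both treated arrays, with untreated signals of 41.5 to 68.0, as was Dcn, a matrix proteoglycan (73.3, 148 and 170), by 1.01 and 1.21 log2. The oxidative phosphorylation list had a median of 0.10 (percentile 99.8) and the cholesterol list 0.15 (percentile 99.5) at 10 µg/ml. At 1 µg/ml their medians were -0.06 (percentile 9.60) and 0.00 (percentile 54.0). The antioxidant and NRF2 target list, with 33 measured genes and none at 2-fold, had a median of 0.07 (percentile 96.7) at 10 µg/ml and -0.02 (percentile 31.7) at 1 µg/ml. No probe set passed adjusted p 0.05 for a dose trend in neurons (limma). Of 4709, 90 had an unadjusted p under 0.05, fewer than the 235 expected by chance. The error shared with the astrocyte arrays may thus be too large for neurons, so the lack of calls says little. Among brighter probe sets, above the 75th percentile, 0 and 1 differed 2-fold at 1 and 10 µg/ml, against 355 and 357 with no signal filter. With 1 value per gene the counts were 5 and 9. Against the mean of both lower doses, 22 probe sets differed at 10 µg/ml.

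The third comparison asked what the extract changed in astrocytes at the doses also given to neurons. At 10 µg/ml, chemokine, cytokine and interferon response genes were higher. Cxcl10, a chemokine induced by interferon, had a signal of 332 untreated and 8879 at 10 µg/ml, 26.8-fold, Rsad2 430 and 11129 (25.9-fold), and Il6, the cytokine interleukin 6, 19.6 and 442 (22.6-fold). Il1a, an interleukin, was 16.2-fold and Cxcl2, a neutrophil chemokine, 15.1-fold higher, and Ptgs2, the inducible cyclooxygenase, and Csf3, a granulocyte growth factor, were at least 12.7-fold and at least 11.7-fold higher, since both untreated signals lay under the floor. Of 27 measured cytokine, chemokine and NF-kB target genes, 22 were at least 2-fold higher and none lower, with a median log2 change of 2.72, and of 14 interferon response genes 9 were higher with a median of 1.05, including Gbp2 (3.06), Irf1 (2.39) and Tap1 (1.74). Both medians lay above all 10000 random lists. So did that of immediate early genes, at 0.47, with 4 of 21 at least 2-fold higher. The ER stress list had a median of 0.23 (percentile 99.6), with 4 of 15 at least 2-fold higher.

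Lower at 10 µg/ml were Id3, an inhibitor of helix-loop-helix transcription factors (-1.25 log2), Slc4a4, a bicarbonate transporter (-1.56), and Ccn1, a matrix protein (-2.34, but 0.34 at 100 µg/ml on the deposited scale). The cell cycle list had a median of -0.45 (percentile 0.05) with no gene at 2-fold, and the ribosomal protein list -0.25 (percentile 0.78). The microglia and macrophage list stood at 0.31 (percentile 99.3), with Cd53 at 1.22 and Fcgr2b at 1.32 and none of its genes at least 2-fold lower. At 1 µg/ml, 3 of the 27 cytokine genes were at least 2-fold higher, with a median of 0.26 above all random lists, Rsad2 was 3.74-fold higher and the microglia list had a median of 0.28. Other lists were low on that array: oxidative phosphorylation (-0.15, percentile 0.05), cholesterol (-0.25, 0.22), extracellular matrix (-0.11, 0.89) and cell cycle (-0.20, 1.19). Extreme percentiles thus also came with small changes. At all 3 doses 22 probe sets were at least 2-fold higher than in untreated cells, with Rsad2, Ifitm10, Gng5, Slc12a7 and P2ry2 the 5 genes farthest apart, and 2 were lower, 1 of them for Igfals. The probe sets of Gng5 went both ways, from -1.02 to 1.80 at 100 µg/ml. In all, 85 of 4252 probe sets differed 2-fold at 1 µg/ml (44 higher, 41 lower) and 277 at 10 µg/ml (183 higher, 94 lower). With the stricter filter these counts were 22 and 115, with 1 value per gene 25 and 136, and with no filter 466 and 728. With no filter more were lower than higher, 291 against 175 at 1 µg/ml and 419 against 309 at 10 µg/ml.

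**Figure D2:**
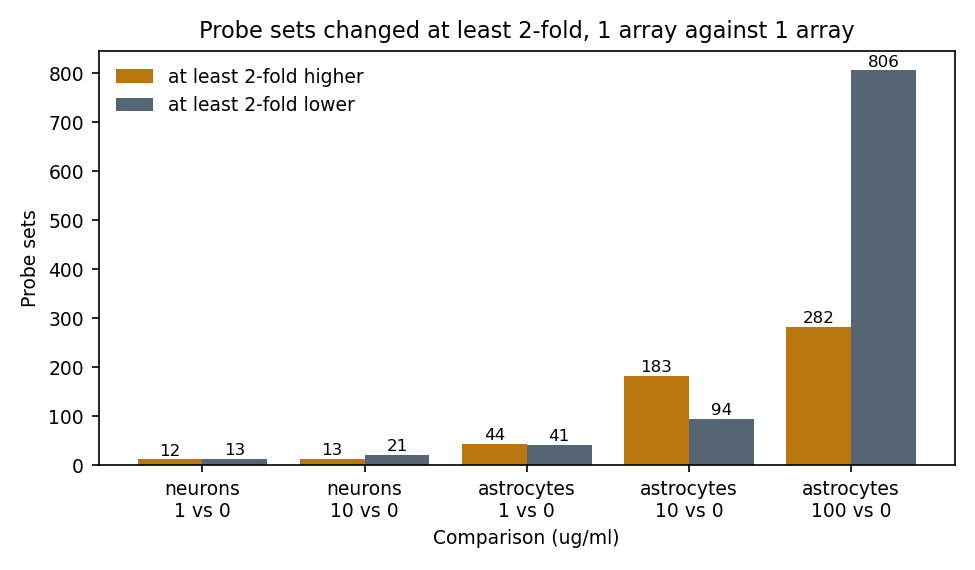
Number of probe sets at least 2-fold higher or lower on each treated array than on the untreated array of the same cell type, on the deposited scale. The total grows from 25 in neurons at 1 µg/ml to 1088 in astrocytes at 100 µg/ml, where 806 were lower. That share of lower probe sets, 74.1%, is 59.3% after quantile normalization.

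At 100 µg/ml the astrocyte array differed most. The median probe set changed by -0.26 log2 on the deposited scale and by -0.09 after quantile normalization, so changes at this dose are given relative to -0.26. Il6 was higher by 10.09 log2 (signals of 19.6, 26.8, 442 and 17783 at 0, 1, 10 and 100 µg/ml), although its probe sets ranged from 6.98 to 9.83 on the deposited scale. Ptgs2 was higher by at least 7.83, Csf3 by at least 7.65, Cxcl2 by 7.06, Il1a by 6.54, Ccl4 by 6.36, Ccl3 by 5.99 and Tnf by 5.71, all genes of inflammation. Immediate early genes stood beside them: Nr4a1, a nuclear receptor, was higher by 6.93, Dusp1, a phosphatase acting on MAP kinases, by 5.51, Fos by 5.36 and Junb by 4.96. Gdf15, a stress-induced cytokine (6.47), Inhba, the activin A subunit (5.10), Tac1 (4.54), Pdp2 (4.38) and Nr4a3 (4.14) were also among the 12 that stood highest above every other astrocyte array. The probe sets of Nr4a3 ranged from -0.03 to 4.82 and those of Tac1 from 1.27 to 4.28 on the deposited scale.

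**Figure D3:**
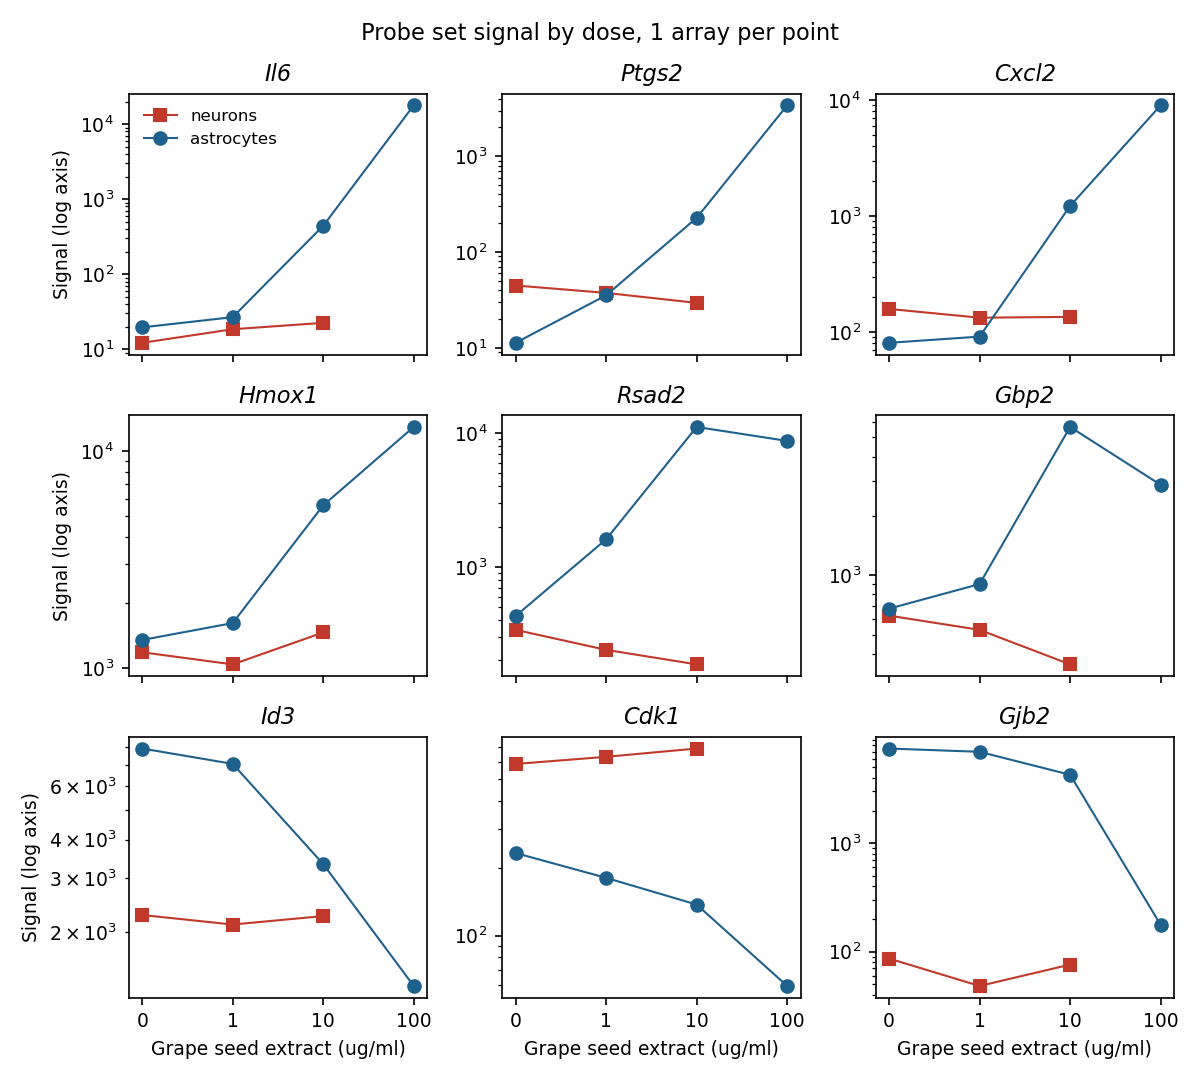
Signal of 9 genes by dose, on log axes, 1 point per array, with neurons as squares and astrocytes as circles. In astrocytes Il6, Ptgs2, Cxcl2 and Hmox1 are highest at 100 µg/ml, Rsad2 and Gbp2 are highest at 10 µg/ml, and Id3, Cdk1 and Gjb2 are lowest at 100 µg/ml.

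At 100 µg/ml the cytokine list had a median of 3.68 relative to all probe sets (21 of 27 at least 2-fold higher on the deposited scale). With counts on the deposited scale too, immediate early genes stood at 2.84 (15 of 21 higher, 2 lower) and ER stress genes at 1.35 (8 of 15). Genes of cholesterol synthesis and uptake stood at 1.27 (8 of 14, 1 lower) and glycolysis and hypoxia genes at 0.66 (4 of 19). Each of these medians lay above all 10000 random lists. Examples are Atf3 (4.95), Ddit3 (4.02) and Trib3 (3.62), transcription and signalling factors of the stress response (the probe sets of Trib3 ranged from -0.69 to 3.36 on the deposited scale), Insig1 (2.60) and Fdps (1.92) of the sterol pathway, and the transporters Slc16a3 (2.11) and Slc2a1 (1.85) for lactate and glucose. The IL-6 and STAT3 list stood at 1.15, with Timp1 at 1.71, and fatty acid synthesis at 0.63, with Acly at 1.62 (probe sets from -0.20 to 2.01 on the deposited scale). Interferon response genes, by contrast, stood at 0.37. On the deposited scale 3 of 14 were at least 2-fold higher, and relative to -0.26 Irf1 was as well (1.22). The signal of Rsad2 was 11129 at 10 and 8749 at 100 µg/ml, that of Gbp2 5654 and 2878, and that of Irf1 12761 and 4720. Measured against the mean of all lower doses, the interferon list's median was -0.17 on the deposited scale. Cxcl10, of the cytokine list, had signals of 8879 and 3556.

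**Figure D4:**
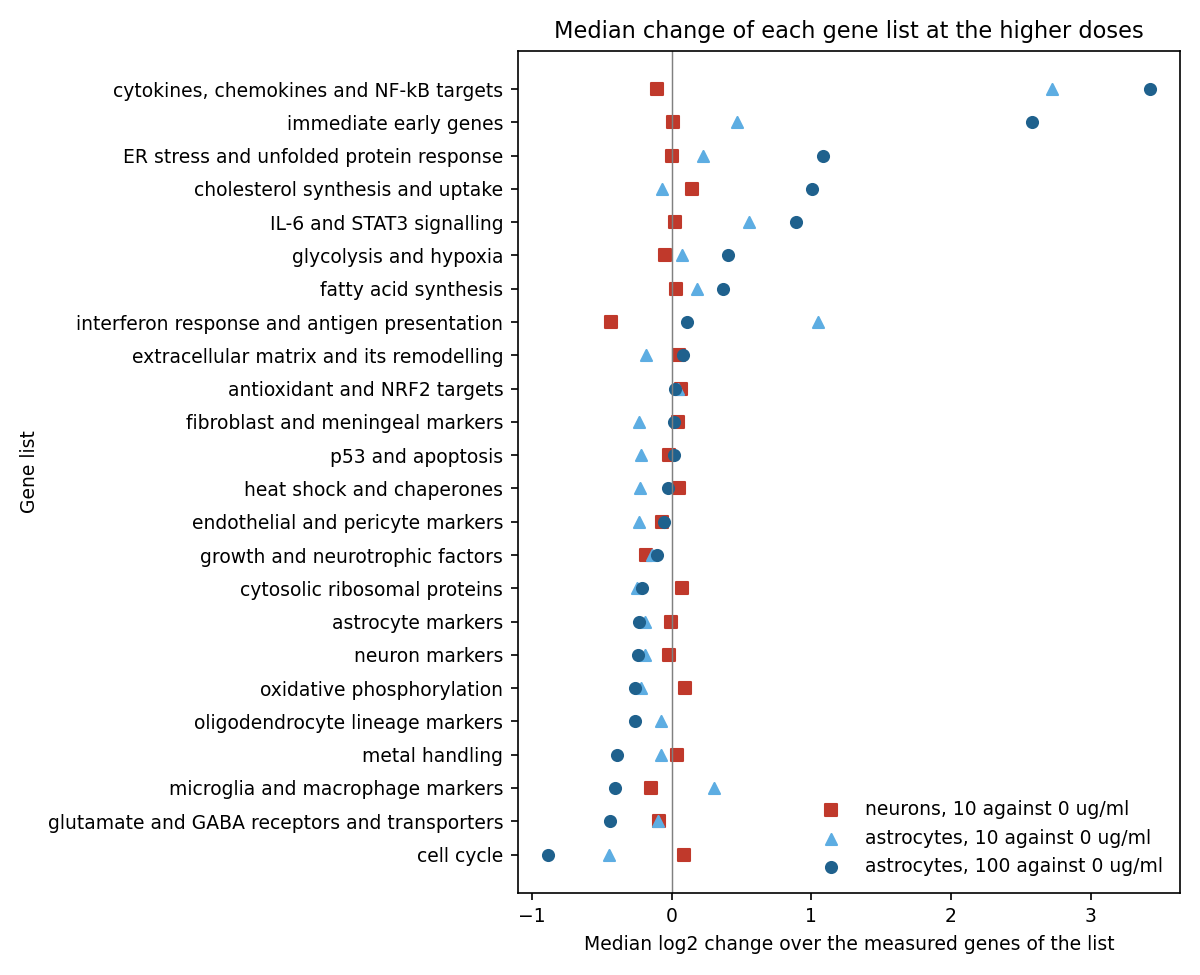
Median log2 change of 24 gene lists on the deposited scale in neurons and astrocytes at 10 µg/ml and in astrocytes at 100 µg/ml, each against the untreated array. Cytokine genes lie farthest right in astrocytes, at 2.72 and 3.42, and cell cycle genes farthest left at 100 µg/ml, at -0.88. Relative to the median probe set at 100 µg/ml (-0.26), lists plotted between -0.26 and 0 turn positive, among them heat shock, growth factor, ribosomal, neuron and astrocyte genes.

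Lower at 100 µg/ml was Gjb2, a gap junction protein, by -5.14 (signals of 7469, 6966, 4278 and 177). Ptpn6, a phosphatase of blood cell lineages, stood at -3.97, P2ry6, a nucleotide receptor, at -3.54, Dock8 at -3.54 and RT1-DMb, a class II histocompatibility gene, at -2.97. Casp2 (-4.54), Crot, Arl11, Mlst8, Ogg1, Tnfrsf21 and Atrx completed the 12 that stood lowest below every other astrocyte array. The probe sets of Casp2 ranged from -4.80 to -0.89, those of Dock8 from -3.81 to -0.88, those of Crot from -3.84 to -1.62 and those of Mlst8 from -3.45 to -0.02 on the deposited scale. The cell cycle list had a median of -0.62 (percentile 0.77). On the deposited scale 8 of its 19 genes were at least 2-fold lower and none higher. Relative to -0.26, Racgap1 (-0.89) was no longer among these, while Mcm5 (-1.92), Cdc20 (-1.84) and Cdk1 (-1.71) were.

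Among markers, Id3 (-2.31), Slc4a4 (-1.89) and Slc1a3 (-1.78, with probe sets from -2.43 to 0.13 on the deposited scale) of the astrocyte list were lower, with a list median of 0.03. The microglia and macrophage list had a median of -0.14, with Aif1 at -2.45 at its brightest probe set (probe sets from -2.71 to 0.35 on the deposited scale) and Fcgr2b (2.49) and Lgals3 (1.55) higher. Medians for the oligodendrocyte, endothelial and pericyte, fibroblast and neuron marker lists were -0.00, 0.21, 0.28 and 0.02. The antioxidant and NRF2 list stood at 0.28 (percentile 93.1), and 29 of its 33 genes stayed within 2-fold on the deposited scale. Hmox1, a heme-degrading enzyme, was higher by 3.52, Sod2, also on the cytokine list, by 2.28 and Nqo1 by 1.45 (its other probe set lay near or under the floor). Gclc stood at -0.77, or -1.03 on the deposited scale, the 1 gene of the list at least 2-fold lower there. Gclm (0.16) and Txnrd1 (0.41) changed little. Extracellular matrix genes had a median of 0.34, with Mmp9 (4.61) and Mmp3 (4.29) higher and Dcn (-1.71, with probe sets from -1.97 to -0.17 on the deposited scale) lower. Growth factor genes had a median of 0.15, with Hbegf at 3.38 (probe sets from 0.35 to 3.12 on the deposited scale) and Bmp4, at or under the floor when treated, at most -3.56. Medians for the p53 and apoptosis, heat shock, oxidative phosphorylation, ribosomal protein, metal handling and glutamate and GABA lists were 0.28, 0.24, -0.00, 0.05, -0.13 and -0.18. On the deposited scale the p53 and apoptosis list had a median of 0.02, with 5 of its 16 genes at least 2-fold lower and none higher. Relative to -0.26, Casp2, Casp6 (-2.34) and Casp1 (-1.32) stayed at least 2-fold lower. Tnfrsf1a (-0.84) and Ccng1 (-0.96) then did not, and Cdkn1a (1.05) was at least 2-fold higher. In all, 1088 of 4252 probe sets differed 2-fold, 282 higher and 806 lower (74.1% lower). The share lower was 59.3% after quantile normalization and 58.9% with changes centred on their median. It was 96.0% when each array was scaled by the median signal of its poly-A spike-ins, 8 control probe sets. That median signal was 142 on the untreated and 288 on the 100 µg/ml astrocyte array. The count was 416 with the stricter filter, 563 with 1 value per gene, 1805 with no filter and 2942 with the spike-in scaling.

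The fourth comparison tested a dose trend within each cell type, a slope of log2 signal on log10 of the dose plus 1. In astrocytes the genes with the smallest adjusted p from limma were again of inflammation: Ptgs2 rose by 3.79 ± 0.15 (SE) log2 per unit (adjusted p = 0.000423), Csf3 by 3.68 ± 0.17 (0.000568), Il6 by 5.08 ± 0.25 (0.000568), Ccl4 by 3.20 ± 0.19 (0.000866) and Il1a by 3.18 ± 0.19 (0.000866). Junb, Ccl3, Icam1 and Cxcl2 rose too, and Id3 fell by 1.33 ± 0.09 (0.000942). These errors and p pool the arrays of both cell types. With astrocytes fitted alone (limma), the adjusted p was 0.0317 for Ptgs2 and Csf3. It was then 0.0365 for Il6, Ccl4 and Id3, and 0.0375 for Il1a. Of 30 cytokine genes 22 rose and none fell (24 adjusted over the list alone). Of 23 immediate early genes 14 rose and Homer1 fell at its brightest probe set (14 and 1 adjusted over the list alone), of 15 ER stress genes 7 rose (10 adjusted over the list alone) and of 20 cell cycle genes 9 fell (10 adjusted over the list alone). Of 14 cholesterol genes 5 rose and Mvk fell (9 and 1 adjusted over the list alone), and of 14 interferon response genes only Rsad2 rose, none when adjusted over the list alone. Among the 11 microglia and macrophage genes Fcgr2b and Lgals3 rose and Aif1 fell.

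In all, 969 of 4709 probe sets were called in astrocytes, 237 up and 732 down, with 3 residual degrees of freedom for the 7 arrays of both cell types. The count was 30 without any 1 of the 3 neuron arrays, and 78, 1694 and 156 without the astrocyte array at 1, 10 and 100 µg/ml. Without 1 neuron array the other neuron arrays are fitted exactly. The error then comes from the astrocyte arrays alone, so the 3 neuron leave-outs are 1 check. Most of the 969 calls thus depended on error information from the neuron arrays. The count was 33 with astrocytes fitted alone, 47 on ranked doses, 10 with no signal filter, 606 with the stricter filter and 577 with 1 value per gene. Most calls stayed down with the stricter filter (167 up, 439 down), 1 value per gene (132 and 445) and without the astrocyte array at 10 µg/ml (424 and 1270). In other settings down calls were lost and most of the rest were up. Without any 1 neuron array 27 were up and 3 down, all among the 969. With astrocytes alone 30 were up and 3 down, and on ranked doses 37 and 10. Without the astrocyte array at 1 or 100 µg/ml 54 and 103 were up and 24 and 53 down, and with no filter 6 were up and 4 down. Calls that held without each array in turn numbered 28 probe sets, 26 of them with a symbol, for 20 genes: Olr1, Il1a, Icam1, Il1b, Hmox1, Pvr, Il6, Zfp36, Junb, Lcn2, Mgp, Ptgs2, Nos2, Ccl4, Ccl3, Csf3, Cxcl2 and Cebpb rose, and Id3 and P2ry12 fell. All other calls named here except Trib3 ended without any 1 neuron array, and then 9 of the 30 cytokine genes and 1 of the 23 immediate early genes were called.

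The last comparison asked whether the response differed between the cell types. The slope of Ptgs2 was 4.35 ± 0.34 (SE) steeper in astrocytes (adjusted p = 0.0343, limma), the only one of 4709 probe sets past the threshold, while 523 had an unadjusted p under 0.05. No call was made with no floor, no filter, the stricter filter, or ranked or untransformed doses, and 4 were made after quantile normalization and 3 with 1 value per gene or a constant prior. None was made without any 1 neuron array or without the astrocyte array at 0 or 1 µg/ml, and 100 and 38 probe sets were called without the astrocyte arrays at 10 and 100 µg/ml. The difference was 4.75 for Il6 (limma, adjusted p = 0.0951) and 3.95 for Csf3 (0.0677). At 10 µg/ml, the log2 changes in the 2 cell types correlated at Pearson's r of -0.11 and Spearman's rho of -0.09 across 3996 probe sets, which are not independent replicates. Within astrocytes, 119 probe sets were higher at both 10 and 100 µg/ml, where independent lists of these sizes would share 12.1, and 94 (10.2 for independent lists) when the 10 µg/ml array was set against the 1 µg/ml array instead, to avoid a shared control. Of the lower probe sets, 60 were shared (17.8 for independent lists), and 47 (15.7) with the 1 µg/ml array as control. Probe sets at least 2-fold above or below every other array of the cell type numbered 10, 10 and 11 for the neuron arrays, and 24, 8, 36 and 661 for the astrocyte arrays in order of dose. With the stricter filter each was lower by more than 1.5 times, for example 0 for untreated and 1 for 10 µg/ml neurons, and 11 and 237 for astrocytes at 0 and 100 µg/ml.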

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

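The tests of the control probe sets, of scaling, of dim probe sets and of microglia were chosen only after the result was seen. The 2 tests of other array assignments were planned. Of the 35 splits of the 7 arrays into 3 and 4, only 1, the real one, called as many as 1423 probe sets. The highest other split called 104. This argues against a random split of the arrays, at the smallest share that 35 splits allow. Of the 24 orders of the doses over the astrocyte arrays, only 1, the real one, called as many as 969, but the order with 0 and 1 µg/ml exchanged called 947. That is the smallest share that 24 orders allow, and it says little about the position of the 2 lowest doses. Reordering cannot tell an effect of dose from aberrant single arrays, since each dose had 1 array, so chance is not excluded.

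Some results differed between neurons and astrocytes. The slope of Ptgs2 differed by 4.35 in the test of the difference itself. Interferon response genes had medians of -0.44 in neurons and 1.05 in astrocytes at 10 µg/ml, and cell cycle genes 0.090 and -0.45, with opposite signs at every dose, and these differences were not tested. All treated neuron arrays lay on the opposite side of their control from all treated astrocyte arrays for Cxcl10 (-0.49 and 4.74 at 10 µg/ml), Rsad2 (-0.86 and 4.70), Dcn (1.21 and -0.71) and Csf3 (-0.40 and 3.55), differences that were not tested either. Such opposite signs were found in 36 of the 182 named genes, 19.8%. With no effect and a shared control 16.7% of unselected genes would have them, but many of these genes were picked by their changes. The 4 genes given here were those beyond 1 SD of the 1 against 0 changes in all 5 treated arrays.

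A signal outside the comparisons was that of the control probe sets. In the astrocyte array at 100 µg/ml the poly-A spike-ins, transcripts added before labelling, were higher than in the untreated array in 8 of 8 probe sets. The median of their changes was 1.40 log2 (0.26 and 0.93 at 1 and 10 µg/ml). Their median signal was 142, 184, 281 and 288 in astrocytes in order of dose, so nearly as high at 10 as at 100 µg/ml. It was 100.4, 65.1 and 138.5 in neurons. The 5S rRNA probe set read 197.7 on the 100 µg/ml astrocyte array, against 3.6 to 9.0 on the other arrays. Brighter hybridization or staining of that array is argued against, since the hybridization controls changed by a median of 0.034 (SD 0.144). Variation in the amount of spike-in added cannot be told apart from a lower share of mRNA in the total RNA, because the neuron arrays, in which few genes differed, varied by 1.01 log2 in the same controls. No biological explanation was tested for it.

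More probe sets were lower than higher in astrocytes at 100 µg/ml. The scaling of the arrays to one trimmed mean is argued against as the whole cause, since 59.3% were lower under quantile normalization and 58.9% with centring, which balances changes around 0 but not beyond 2-fold, down from 74.1%. Noise of dim probe sets is argued against by 64.7% lower among those above the 75th percentile, although this was 53.3% when the changes were also centred, so both acting together stay open. Loss of microglia cannot be told apart from the other explanations: their list's median was -0.40, against -1.50 for the lower probe sets, but its members went both ways with an SD of 1.26, and Ptpn6, P2ry6, Dock8 and RT1-DMb, genes also known from myeloid cells and picked after their values were seen, were among the lowest. An effect of the dose on the astrocytes stays open, as untested against a single aberrant array.

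Cytokine and NF-kB target genes were higher in astrocytes at 10 and 100 µg/ml. Scaling is argued against by a lowest median of 1.74 over quantile normalization, centring and spike-in scaling. More microglia in the treated cultures is argued against by their list's median of 0.31 at 10 µg/ml, where the cytokine list's was 2.72. The bootstrap SE of 0.31 over the list's genes was 0.236, which holds no variation between cultures. Activation of the microglia and other cells already present, as a response to the extract or to something carried with it, may explain the pattern and was not tested. The labels give a single array for each dose, so a difference between cultures also stays open.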

How the results depend on the processing

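Centring, the 1 µg/ml reference and spike-in scaling were chosen only after the result was seen. Counts of 2-fold changes in neurons at 1 and 10 µg/ml and astrocytes at 1, 10 and 100 µg/ml were 355, 357, 466, 728 and 1805 with no filter, 0, 1, 22, 115 and 416 with the stricter filter and 5, 9, 25, 136 and 563 per gene. These settings test more or fewer items. Against the mean of lower doses neurons at 10 µg/ml gave 22, and with spike-in scaling astrocytes at 100 µg/ml gave 2942, and the cause was not tested. Quantile normalization, no floor, centring and, in astrocytes, the other references kept each of these counts within 1.5 times. The astrocyte trend count of 969 was 10 with no filter, 606 with the stricter filter, 577 per gene, 47 on ranked doses, 33 with astrocytes alone and 30 to 1694 leaving out 1 array. The difference of trends (1) was 4 with quantile normalization, 3 per gene and with a constant prior, 0 with no floor, no filter, the stricter filter, ranked or untransformed doses, and 0 to 100 leaving out 1 array. Without 1 neuron array the other neuron arrays are fitted exactly. The error then comes from the astrocyte arrays alone, so the 3 neuron leave-outs are 1 check. Beyond this and fewer arrays or items, the cause was not tested for either trend. The neuron trend gave 0 under every alternative. That says little, since in the main fit fewer unadjusted p lay under 0.05 than expected by chance. The comparison of cell types gave 892 with the stricter filter, 795 per gene and 937 to 2086 leaving out 1 array. Probe sets apart numbered 6 for untreated neurons with quantile normalization, and with the stricter filter 0 and 1 for neurons at 0 and 10 µg/ml and 11 and 237 for astrocytes at 0 and 100 µg/ml. For 314 named-gene changes the yardstick was the SD over probe sets of the change from 0 to 1 µg/ml in that cell type. Smaller moves were seen for 285 under quantile normalization, 312 with no floor, 252 against the mean of lower doses and 245 as the mean over probe sets. Thpol1 in neurons at 10 µg/ml reversed to 0.028 as the mean over its probe sets, and the cause was not tested. For 71 list medians the yardstick was the SD of the median over bootstrap draws of the list's genes, which holds no variation between arrays. Smaller moves were seen for 66 under quantile normalization, 71 with no floor, 49 with centring and 38 of the 47 set against lower doses. Signal over background limits what is seen: at least 23.3% of probe sets on each array were at the floor, and the count of 2-fold changes in neurons came from dim probe sets, with 0 and 1 above the 75th percentile.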

Other observations

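No test in this part was chosen only after the result was seen, but the genes named were. The trend without the 100 µg/ml astrocyte array was a fit decided on in advance. Each dose in it had a single array per cell type, and its error came partly from the neuron arrays. A slope in astrocytes can rest mainly on the 10 µg/ml array, so an effect of dose cannot be told from an aberrant array. The fit gives the genes whose signals had a slope over the astrocyte arrays from 0 to 10 µg/ml. Among those with an adjusted p from limma under 0.05 were several not described above: Ccl2 rose by 3.97 and 2.51 log2 per unit at its probe sets, Vcam1, an adhesion molecule for leukocytes, by 2.58, Cx3cl1, a chemokine for microglia, by 2.76, Ccl20 by 6.31 and Irgm2, an interferon-induced GTPase, by 2.41. Gch1, the first enzyme of tetrahydrobiopterin synthesis, rose by 3.26, and Cd200, a ligand that restrains myeloid cells, by 2.32. Cnn1, a smooth muscle protein, fell by 1.82, Fst, an activin inhibitor, fell by 2.35, and Agtr1a, an angiotensin receptor, fell by 3.56. In that fit 156 probe sets were called, 86 of them shared with the 969 of all arrays, and Il1a, Rsad2, Cxcl10, Irf1, Cebpb and Hmox1 were also among the smallest adjusted p.

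Several of these genes had lower signals at 100 than at 10 µg/ml, such as Vcam1 (827, 1559, 5461 and 1609 at 0, 1, 10 and 100 µg/ml), Cx3cl1 (726, 1078, 5105 and 1700.4) and Mx1 (166, 194, 862 and 158). Pdgfra, a growth factor receptor of progenitor cells and fibroblasts, was also highest at 10 µg/ml (3730.1, 4950 and 7780 at 0, 1 and 10 µg/ml). At 100 µg/ml, however, it lay well below its untreated signal (1232). Ccl20 did not (45.1, 72.5, 3475 and 6884). No test compared 10 with 100 µg/ml, since each was a single array.

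The ratio of the 3' to the 5' probe set of Gapdh, a measure of transcript length after labelling, was 2.67, 3.24 and 2.73 in neurons and 2.66, 2.63, 2.42 and 1.90 in astrocytes in order of dose. That of beta-actin was 10.5, 10.5 and 10.8 in neurons and 8.95, 8.92, 9.29 and 10.6 in astrocytes.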
